A study of Mus musculus with 2 samples.

How the data were processed

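Total RNA from the hippocampus of 2 adult female mice was sequenced as 2 libraries, 1 per animal. The mice were B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ, aged 8 to 10 months. Per the labels, the libraries came from animals 1 and 5 and are biological replicates 1 and 2, each made from 300 ng of RNA with ERCC spike-ins, synthetic transcripts added at known amounts. The labels also give both samples the same donor identifier. They were taken as 2 animals from their animal numbers, and every SD and ratio between animals rests on this reading. The labels name a directional library kit with reduced ribosomal RNA. The tissue term in the labels is a layer of the hippocampus, and which layer or how it was dissected is not given in the sources used here. Both animals share sex, age range and strain, so they form 1 group, and no comparison between conditions exists.

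Each library has a gene table and 2 transcript tables on mouse build mm10 (GRCm38) with GENCODE M21, per the accompanying file notes. The gene table and the first transcript table have the column layout of RSEM, and the second transcript table has that of kallisto, per the file headers. The aligner, the versions of these tools and whether counting used strand are not given in the sources used here. Expected counts, which share reads among matching genes and so need not be whole, were deposited without normalisation. The second transcript table holds estimated counts, deposited per transcript and made from a single FASTQ file of each library, per the accompanying file notes. TPM was deposited after length normalisation by the authors and includes mitochondrial and spike-in entries. FPKM was deposited by the authors in the gene table and was used here for an alternative only. The percent of a gene's TPM held by each transcript was deposited in the first transcript table and was recomputed from TPM here. The posterior SD of each count was deposited as a signal in counts, per the file headers, and covers read assignment only. The deposited bounds of TPM give no level in their header and were not used.

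Expected counts totalled 34208349 in replicate 1 and 28417193 in replicate 2. The second transcript table held 36354349 and 30279119 estimated counts on annotated genes. The gene table lists 81881 entries, of which 55536 are annotated genes, 26248 carry numeric identifiers that match no GENCODE gene, 96 are spike-ins and 1 is phiX. Only annotated genes entered library sizes. Spike-ins, left out of them, held 0.178% of counts in replicate 1 and 0.212% in replicate 2, and phiX and the numeric identifiers held 79 and 4 counts in replicate 1 and 71 and 0 in replicate 2. Symbols, biotypes and coordinates came from GENCODE M21, and all 55536 gene identifiers matched. RefSeq on the same build served only to name the locus of Gm42418.

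Levels are the mean TPM ± SD over 2 animals. A gene counted as detected at a TPM of at least 1. A difference in level between genes is stated where the gap exceeded the SD of both and had the same sign in both animals. Expected counts were rounded to whole numbers before any ratio was formed. Ratios of replicate 2 over replicate 1 used TMM scaling in edgeR 4.0.16 with a prior count of 2, under R 4.3.3. Effective library sizes were 34038040 and 28448001 counts. The criterion for a gene differing at least 2-fold was a log2 ratio of at least 1 in size, a mean count of at least 50 and an exact Clopper-Pearson 95% interval of the ratio that excluded 1. This criterion compares 2 libraries, not conditions. Intervals of ratios and of spike-in shares, and count floors, cover counting error only, since the labels name no molecular identifiers. No p-value was computed. A gene with a count of 0 in 1 library was given a lower bound of its fold against a floor of 3 counts in that library. Read assignment was called uncertain where the posterior SD, in the library with the larger count, exceeded 2 times the square root of that count, which took in 1.35% of the 14434 genes tested. Antisense and overlapping genes cannot be separated without the strand setting and are reported as a class only.

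Gene lists were fixed before the data were examined, as were the criterion, the rule for named genes and the alternatives, except those given as chosen later. The lists numbered 46 with 403 entries and 385 distinct genes, all 385 of which matched. For 44 lists with at least 3 members at a mean count of at least 10, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The named genes were the 10 nuclear protein-coding genes of highest TPM, the 2 highest members and the lowest member of each list, list members meeting the 2-fold criterion, all members of the receptor, neuropeptide, neurotrophin and sex-linked lists, the 10 genes with the largest ratio in each direction, and up to 8 isoform genes. Some genes that this rule takes in are not reported here. Any other gene is named as chosen after its value was seen. The dispersion, as the biological coefficient of variation, was estimated in edgeR with an intercept only. The highest transcript of each gene was compared between animals and between tables for genes with at least 2 transcripts and a TPM of at least 5.

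The criterion was tested on simulated data with 200 changed genes among 14433 tested. These were drawn from the measured means and depths, with the same common spread between animals for every gene. It recovered 9% of genes changed 1.5-fold, 50% at 2-fold, 93.5% at 3-fold and 96% at 4-fold, and called 6 to 8 unchanged genes. Errors of read assignment were not simulated, so more unchanged genes may be called in the measured data. A simulated change of 2-fold lies at the cutoff itself, so its recovery does not measure depth. Of 100 random lists of 10 genes, 7 fell outside the central 95% without a shift and 100 did with a log2 shift of 0.5. GC content and transcript length were known for 18601 genes, 99.9% of those with a mean count of at least 10. The alternatives were DESeq2 1.42.0 size factors, spike-in scaling, TPM as deposited, other count minimums and prior counts, the second transcript table, other TPM minimums and pseudocounts, FPKM, classes of entries left out, and each replicate left out. Added after seeing the data were a correction for GC content and length in 10 bins of each, and counts without choroid plexus markers or without genes of uncertain read assignment. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Allele-specific expression was not analysed here, since the tables used do not separate the parental alleles.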

Results

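Total RNA was sequenced from the hippocampus of 2 adult female B6CASTF1/J mice aged 8 to 10 months, 1 library per animal. The libraries form 1 group, so the values describe transcript levels in this tissue and the spread between 2 animals, and no conditions were compared. Depth was 34208349 expected counts in replicate 1 and 28417193 in replicate 2. Levels are given as mean TPM ± SD with n = 2, and ratios as replicate 2 over replicate 1. Coordinates are on mm10 with GENCODE M21.

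The first question was which RNAs made up the hippocampal transcriptome. Nuclear protein-coding genes held 81.3 ± 0.33% of the counts. Mitochondrial ribosomal RNA held 5.94 ± 0.056%, led by mt-Rnr2 at 45975 ± 941 TPM. The 7SL RNA of the signal recognition particle, which brings nascent secretory proteins to the endoplasmic reticulum, held 3.21 ± 0.028% of the counts through Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481). These copies had identical values, so their reads were shared equally and cannot be told apart. Because 7SL is short, it held 25.95 ± 0.12% of TPM, and protein-coding genes held 49.9 ± 0.23%. The 7SK RNA, a regulator of transcription elongation, held 0.438 ± 0.032% of the counts from Rn7sk (chromosome 9, 78175303 to 78175633). A pair of adjoining loci on chromosome 17, Gm26917 (39843013 to 39846341) and Gm42418 (39846958 to 39848788), held 2.43 ± 0.032%. RefSeq lists Gm42418 as a synonym of Rn18s-rs5, a pseudogene related to 18S ribosomal RNA, at 39846354 to 39848202. Other long intergenic noncoding RNAs held 2.57 ± 0.18%.

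Of 55536 annotated genes, 15245 reached a TPM of at least 1 in both animals, from 15917 in replicate 1 and 16136 in replicate 2. Protein-coding genes made up 13023 of them, which was 59.1% of the 22028 annotated. Long intergenic noncoding RNAs contributed 317 of 5854 annotated and antisense genes 207 of 2959, the latter uncertain because the strand setting of the counting is not known. A TPM of at least 100 was reached by 1045 genes in both animals.

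Among nuclear protein-coding genes, Fth1, the heavy chain of the iron store ferritin, had the highest mean at 1656 ± 57 TPM, but its gap to Camk2a was smaller than the SD of Camk2a. Camk2a, the alpha subunit of the calcium/calmodulin-dependent kinase of excitatory synapses, reached 1559 ± 104 TPM (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152). Actb, cytoplasmic actin, stood at 1485 ± 129 TPM. The glycolytic enzymes Gapdh and Aldoa reached 1446 ± 7.8 and 1390 ± 25 TPM. Cpe, which processes neuropeptide precursors, reached 1356 ± 13 TPM, and the elongation factor Eef1a1 1255 ± 19 TPM. Hpca, the calcium sensor hippocalcin, stood at 1065 ± 121 TPM, and Snap25, a component of the vesicle fusion machinery, at 1064 ± 33 TPM.

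Markers of the hippocampal subfields were present for each principal cell type. Of the dentate granule cell markers, 11 of 11 reached a TPM of 1 in both animals, with C1ql2, a secreted synaptic protein, at 40.2 ± 8.4 TPM, Stxbp6 at 39.3 ± 1.5 TPM and Tdo2, a tryptophan-degrading enzyme, lowest at 3.97 ± 0.64 TPM. All 7 CA1 markers did so, led by Wfs1 at 106 ± 29 TPM and Mpped1 at 94.8 ± 2.3 TPM. In CA2 the count was 5 of 6, with the calmodulin regulator Pcp4 at 103 ± 10.5 TPM, the signalling regulator Rgs14 at 44.3 ± 1.3 TPM and the kinase Map3k15 at 0.625 ± 0.092 TPM. In CA3 it was 8 of 8, with Cpne4 at 63.4 ± 2.4 TPM, the BCL2 family member Bok at 31.6 ± 6.5 TPM and Coch at 1.95 ± 0.49 TPM. Mossy cell markers were at 3 of 4, with Ajap1 at 22.4 ± 0.53 TPM, the calcium buffer Calb2 at 19.9 ± 0.11 TPM and Csf2rb2 at 0.645 ± 0.035 TPM. The general glutamatergic markers were all detected, from Camk2a and Nrgn, a postsynaptic calmodulin-binding protein at 629 ± 74 TPM, down to the transcription factor Neurod1 at 11.1 ± 1.3 TPM.

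Inhibitory neurons were represented by 12 of 12 markers. The neuropeptide Sst stood at 190 ± 17.5 TPM and Gad1, which makes GABA, at 184 ± 11 TPM, a gap smaller than either SD. Dlx1, a transcription factor of the interneuron lineage, was the lowest at 7.39 ± 0.87 TPM. Of the Cajal-Retzius cell markers only Ndnf, at 7.19 ± 0.099 TPM, and Trp73, at 1.21 ± 0.29 TPM, reached a TPM of 1 in the mean, and Lhx5 had 3 counts in replicate 1 and 0 in replicate 2. Markers of newborn neurons and dividing cells were low, with 2 of 8 detected. They were Dcx, a microtubule protein of migrating neurons, at 6.38 ± 0.78 TPM, and Sox11 at 5.52 ± 2.9 TPM, and the progenitor factor Eomes was lowest at 0.110 ± 0.071 TPM.

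Glial and vascular markers were detected almost throughout. Astrocytes had 11 of 11 markers, led by the glutamate transporter Slc1a2 at 845 ± 35 TPM and the aldolase Aldoc at 368 ± 17 TPM, down to Sox9 at 13.5 ± 0.099 TPM. Oligodendrocytes had 11 of 11, led by the myelin protein Mbp at 736 ± 23 TPM, down to Opalin at 7.0 ± 3.1 TPM. Their precursors had 6 of 6, from the growth factor receptor Pdgfra at 17.3 ± 0.52 TPM and Gpr17 at 11.1 ± 2.3 TPM to Neu4 at 3.73 ± 0.40 TPM. Microglia had 11 of 11, with the receptor Csf1r at 32.1 ± 2.9 TPM and Aif1 lowest at 4.03 ± 1.4 TPM. Endothelial cells had 10 of 10, from Ly6c1 at 31.0 ± 0.91 TPM and the anion transporter Slco1a4 at 19.9 ± 5.5 TPM to Emcn at 3.07 ± 0.80 TPM. Mural cells had 9 of 10, from Vtn at 35.3 ± 5.9 TPM and Rgs5 at 27.3 ± 2.3 TPM to Kcnj8 at 0.805 ± 0.021 TPM. Blood was present in the tissue, with the haemoglobin chains Hbb-bs at 125 ± 1.9 TPM and Hba-a1 at 109 ± 6.5 TPM and the haem synthesis enzyme Alas2 at 1.61 ± 0.33 TPM. Perivascular macrophage markers were at the edge of detection, 1 of 6, with Mrc1 at 1.52 ± 0.36 TPM and Lyve1 at 0.575 ± 0.39 TPM.

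Genes chosen as markers of neighbouring regions were also present. These lists are not exclusive to their regions, and hippocampal cells express several of their members. Markers of striatal neurons were detected in 7 of 8, from the phosphodiesterase Pde10a at 28.7 ± 0.99 TPM and the phosphatase regulator Ppp1r1b at 28.3 ± 3.5 TPM to the adenosine receptor Adora2a at 1.02 ± 0.38 TPM. Thalamic markers were detected in 6 of 7, from the kinase Prkcd at 16.5 ± 1.9 TPM and the glutamate transporter Slc17a6 at 10.1 ± 0.049 TPM to the troponin Tnnt1 at 1.11 ± 0.67 TPM. Neocortical markers were detected in 7 of 8, from Tshz2 at 37.3 ± 1.1 TPM and Cux2 at 26.7 ± 4.4 TPM to Nxph4 at 1.11 ± 0.21 TPM. All 3 subicular genes were detected, with fibronectin, Fn1, at 28.0 ± 4.4 TPM, Nts at 7.02 ± 1.2 TPM and Tpbg at 4.08 ± 1.1 TPM. Ependymal markers were detected in 4 of 6, from Rarres2 at 7.52 ± 0.76 TPM and Ccdc153 at 2.52 ± 1.9 TPM to Mia at 0.885 ± 0.91 TPM.

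Receptor subunits were unequally expressed. Among AMPA receptor subunits, which carry fast excitation, Gria1 at 389 ± 15 TPM exceeded Gria2 at 325 ± 5.9 TPM in both animals, and Gria3 and Gria4 followed at 89.1 ± 10 and 29.4 ± 1.8 TPM. Among NMDA receptor subunits, the obligatory Grin1 at 212 ± 18 TPM did not stand apart from Grin2a at 194 ± 19 TPM, and both exceeded Grin2b at 142 ± 4.9 TPM. Grin2c, Grin3a and Grin2d were lower at 20.6 ± 0.23, 14.9 ± 1.2 and 5.46 ± 0.52 TPM, and Grin3b had 3 counts in replicate 1 and 1 in replicate 2. Kainate receptors were led by Grik5 at 116 ± 13 TPM, with Grik1 lowest at 8.04 ± 0.35 TPM. Metabotropic glutamate receptors were led by Grm5 at 119 ± 5.5 TPM, with Grm8 lowest at 6.11 ± 1.7 TPM. Among GABA-A receptor subunits, which carry fast inhibition, Gabra5 stood at 87.7 ± 14 TPM, and Gabra6 had 1 count in replicate 1 and 5 in replicate 2. The serotonin receptors Htr2c, Htr1a and Htr4 lay at 15.8 ± 0.22, 15.2 ± 5.2 and 14.99 ± 1.9 TPM, and Htr6 was lowest at 4.17 ± 0.24 TPM.

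**Figure D1:**
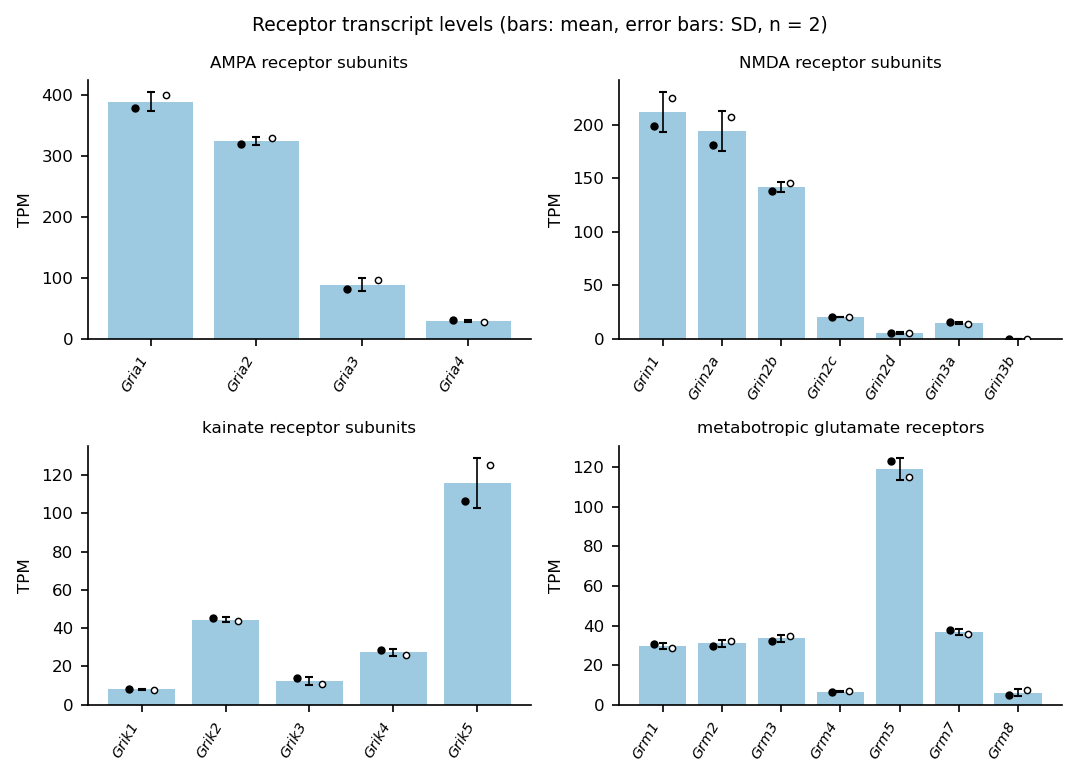
Transcript levels in TPM of AMPA, NMDA and kainate receptor subunits and of metabotropic glutamate receptors, with bars for the mean, error bars for the SD, filled points for replicate 1 and open points for replicate 2. Gria1 at 389 TPM, Grin1 at 212 TPM, Grik5 at 116 TPM and Grm5 at 119 TPM had the highest mean of their panels, and Grin1 did not stand apart from Grin2a by more than the SD.

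Corticosteroid receptors were the most abundant steroid receptors. The mineralocorticoid receptor Nr3c2 at 76.3 ± 1.7 TPM exceeded the glucocorticoid receptor Nr3c1 at 40.9 ± 4.9 TPM in both animals. The progesterone receptor Pgr was lower at 7.15 ± 0.33 TPM and the oestrogen receptor Esr1 at 2.01 ± 0.41 TPM, and Esr2 stood at 0.170 ± 0.071 TPM. Cck was the leading neuropeptide at 255 ± 11 TPM, above Sst, with Npy at 53.8 ± 6.7 TPM, Penk at 28.1 ± 14 TPM and Crh lowest at 1.20 ± 0.51 TPM. The neurotrophin receptors Ntrk2 and Ntrk3 reached 157 ± 2.2 and 101 ± 13 TPM, and Bdnf, the ligand of Ntrk2, 18.5 ± 4.2 TPM. Xist, the noncoding RNA that silences an X chromosome in females, stood at 108 ± 2.9 TPM. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 4 counts each in either library.

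Further lists covered imprinted, housekeeping, noncoding and immune genes. Imprinted genes were detected in 19 of 21, led by the noncoding RNAs Meg3 at 1458 ± 26 TPM and Rian at 597 ± 13 TPM, and H19 was lowest at 0.190 ± 0.071 TPM. Mitochondrially encoded mRNAs ranged from mt-Co1, a subunit of cytochrome oxidase, at 7120 ± 379 TPM to mt-Nd6 at 210 ± 30 TPM, and mt-Co3, with uncertain read assignment, reached 4453 ± 735 TPM. Nuclear genes of oxidative phosphorylation ranged from the ATP synthase subunit Atp5b at 849 ± 17 TPM and Cox4i1 at 487 ± 8.5 TPM to Ndufs1 at 79.5 ± 3.5 TPM. Cytosolic ribosomal proteins ranged from Rps14 at 402 ± 27 TPM and Rpl4 at 262 ± 0.63 TPM to Rplp0 at 93.0 ± 2.7 TPM. Of the noncoding RNAs, Rn7sk stood at 30673 ± 2337 TPM, the nuclear speckle RNA Malat1 at 8152 ± 740 TPM and the paraspeckle RNA Neat1 at 36.8 ± 2.9 TPM. Interferon-stimulated genes were detected in 3 of 8, from Ifi27 at 57.4 ± 0.45 TPM and Bst2 at 2.39 ± 0.099 TPM to Usp18 at 0.205 ± 0.049 TPM. MHC class I genes were detected in 5 of 5, from B2m at 57.5 ± 3.5 TPM and H2-K1 at 15.3 ± 1.7 TPM to the peptide transporter Tap1 at 1.98 ± 0.39 TPM.

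The second question was how far the 2 animals agreed. Between them, log2(TPM + 1) had a Pearson r of 0.977 and a Spearman rho of 0.979 across 16061 genes, which are not independent replicates. The common biological coefficient of variation was 0.119 over 14434 genes. The median absolute log2 ratio was 0.14 over these genes, from 0.25 in 3315 genes at mean counts of 50 to 200 to 0.07 in the 1157 genes of highest count. The counting interval excluded a ratio of 1 in 6393 genes, or 44.3%, where counting error alone would give about 5%.

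**Figure D2:**
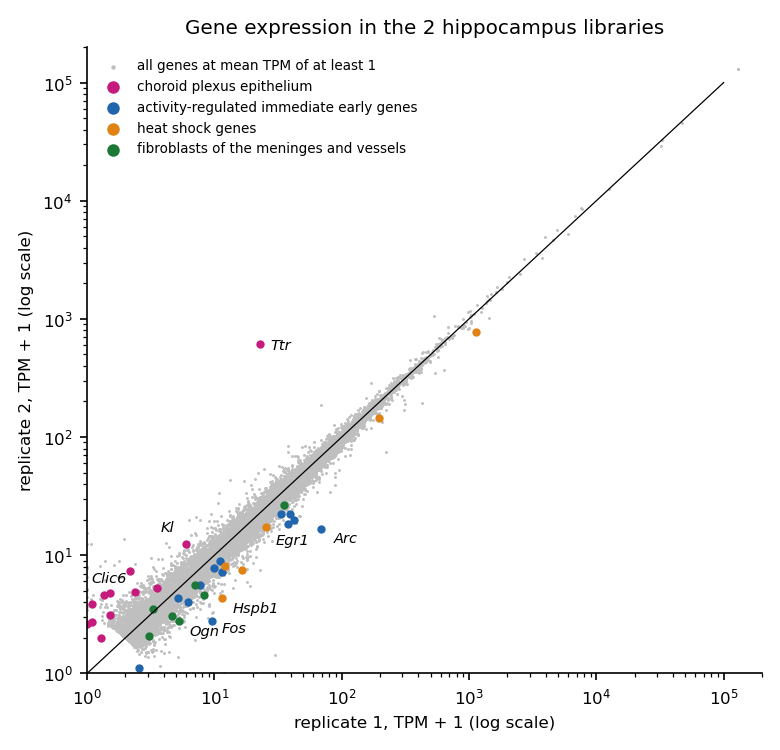
TPM + 1 in replicate 1 (horizontal, log scale) against replicate 2 (vertical, log scale), with a line of equal level. Grey points are genes with a mean TPM of at least 1 and a mean count of at least 10. Members of 4 lists are in colour, whatever their level. Choroid plexus markers such as Ttr, at 21.8 against 615 TPM, lie above the line, and Arc, at 67.7 against 15.8 TPM, lies below it.

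Between the animals, 159 of 14434 genes, 1.10%, differed at least 2-fold, 85 higher and 74 lower in replicate 2. The highest ratio among well assigned known genes belonged to Ttr, the thyroid hormone carrier transthyretin of the choroid plexus (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321). It went from 498 to 11764 counts, 28.1-fold higher, with a log2 ratio of 4.81 and an interval of 4.69 to 4.95. Aqp1, a water channel, was 21.5-fold higher, with a log2 interval of 3.67 to 6.57 (chromosome 6, 55336432 to 55348555). Mfrp and the bicarbonate transporter Slc4a5 were 16.7-fold and 13.2-fold higher. The remaining 6 of the 10 genes with the largest increases were Tmem254b and 5 predicted genes or pseudogenes. Gm10600 and Gm13301, neighbours on chromosome 4, had 0 counts in replicate 1 and were at least 47.5-fold and 43.1-fold higher, and Gm17167, which overlaps Gm13301 on the same strand and so is not a separate locus, was 25.1-fold higher. The second transcript table gave these 3 genes log2 ratios of 7.26, 5.52 and 1.78, and Gm13301 did not meet the criterion there. Gm20388, at 6.51 against 783.55 expected counts, Tmem254b, and Gm2274, at 0 against 103.48 expected counts, had uncertain read assignment, and the second transcript table gave Gm20388 and Tmem254b log2 ratios of 1.10 and 0.39 and held less than 1 count of Gm2274, so no ratio was measured for it. This was also so for 7 of the 10 genes with the largest decreases, which were Pagr1a, Gm28539, Nnt, Hist1h4n, Gm2260, Gm49388 and Gm9794.

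The predicted gene Gm10778 had the largest decrease among genes under the cutoff for uncertain read assignment, 4.66-fold with a log2 ratio of -2.22. It lay close to that cutoff of 2, with a posterior SD of 1.87 times the square root of its larger count. The second transcript table gave it -1.03. The immediate early genes Fos and Arc followed. Fos, a transcription factor switched on by neuronal activity, went from 281 to 49 counts, 4.66-fold lower, with a log2 ratio of -2.22 and an interval of -2.73 to -1.82 (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273). Arc, a postsynaptic protein of synaptic plasticity, went from 4215 to 824 counts, 4.27-fold lower, with a log2 ratio of -2.09 and an interval of -2.21 to -1.99 (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570). The largest decreases of all had uncertain read assignment and were smaller or absent in the second transcript table. Pagr1a, at 642.1 against 2.42 expected counts, had a log2 ratio of -7.14 in the gene table and -1.41 in the second. Gm28539, the Nnt entry ENSMUSG00000116207.1, Hist1h4n and Gm2260 had 267.15, 142.86, 141.34 and 128.88 expected counts in replicate 1 and 0 in replicate 2, against log2 ratios of -0.83, 0.03, -2.08 and -0.10 in the second table, where Hist1h4n had only 7 and 0 counts. Of the 159 genes, 28 had uncertain read assignment and 103 also differed at least 2-fold in the second transcript table. Under spike-in scaling the split was 46 higher and 168 lower, or 21.5% higher against 53.5% under TMM.

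Of 44 gene lists, 9 had a median log2 ratio outside the central 95% of 10000 random lists. Chance would give 2.2 if genes varied independently, which members of these lists need not do. Choroid plexus epithelium stood furthest apart, with 12 of 12 markers higher in replicate 2 and a median of 2.46 at percentile 100. Only 5 of these 12 markers reached a TPM of 1 in both animals, and Ttr, the most abundant, stood at 21.8 TPM in replicate 1 and 615 TPM in replicate 2. Of these, 7 met the 2-fold criterion, and besides Ttr, Aqp1 and Slc4a5 they were the chloride channel Clic6 at 3.26, the BMP antagonist Sostdc1 at 2.37, the potassium channel Kcnj13 at 1.45 and the FGF co-receptor Kl at 1.20. Kl met it no longer under spike-in scaling, at 0.96. Kcne2, a potassium channel subunit, had 0 and 45 counts, at least 17.9-fold higher, a value on the same side of the list median as its fitted ratio. The lowest marker by mean level, the tight junction protein Cldn2, was at 0.640 ± 0.51 TPM.

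Activity-regulated immediate early genes were lower in replicate 2 in 13 of 13, with a median log2 ratio of -0.76 at percentile 0. Besides Fos and Arc, the transcription factors Egr1 and Nr4a1 met the 2-fold criterion at -1.12 and -1.07. Junb, at 30.0 ± 12 TPM, had a ratio of -0.84, and Egr2, the lowest by level at 0.840 ± 1.0 TPM, had 92 against 6 counts, under the count minimum. Heat shock genes were lower in 6 of 6, with a median of -0.62 at percentile 0. The small chaperone Hspb1 at -1.62 and the inducible Hspa1b at -1.24 met the criterion, and the abundant chaperones Hspa8 and Hsph1, at 951 ± 259 and 171 ± 36 TPM, had ratios of -0.55 and -0.41. Fibroblasts of the meninges and vessels were lower in 6 of 7 genes, with a median of -0.69 at percentile 0. The proteoglycan Ogn met the criterion at -1.26, while Dcn at 30.1 ± 6.1 TPM, Slc6a13 at 5.41 ± 2.6 TPM and the collagen Col3a1 at 1.55 ± 0.69 TPM had ratios of -0.42, -0.92 and -0.69. Perivascular macrophage markers were lower in 5 of 5 tested, with a median of -0.58 at percentile 0.93, and the transglutaminase F13a1 met the criterion at -1.20 but not in the second transcript table, at -0.82.

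Smaller list shifts went towards replicate 2. Striatal markers had a median log2 ratio of 0.30 at percentile 99.7, oligodendrocytes 0.16 at percentile 99.9, NMDA receptor subunits 0.14 at percentile 99.2 and mitochondrially encoded mRNAs 0.11 at percentile 99.7. The medians of oligodendrocytes, NMDA receptor subunits and mitochondrial mRNAs fell under 0 with spike-in scaling, at -0.085, -0.098 and -0.135. That scaling lowers all genes by nearly the same amount, and random lists move with them. Their percentiles under it, 99.9, 99.2 and 99.7, were therefore fixed in advance and are no check of these shifts. After the correction for GC content and length, mitochondrial mRNAs had a median of 0 at percentile 36.2 and lost their shift. With TPM as deposited, striatal markers at 0.13 and NMDA receptor subunits at 0.12 came inside the central 95%. Spike-in scaling moved the scale between the libraries by -0.24 and the median of all genes to -0.26. Among the lists inside the central 95%, glutamatergic neurons had a median of 0.05, GABAergic interneurons -0.08, astrocytes -0.06, microglia 0.04, CA1 cells 0.03, CA3 cells -0.17, dentate granule cells -0.06 and ependymal cells 0.22. Single members of such lists met the 2-fold criterion. The neurogenic factor Sox11 was at -1.14, the clock-controlled repressor Ciart at 1.38, and the kinase Sgk1 at 1.05, or 0.80 under spike-in scaling and then under the criterion. From the shifted list of mitochondrial mRNAs, mt-Co2 was at -1.14 with uncertain read assignment, and at 0.60 in the second transcript table. The leading and lowest glucocorticoid-responsive genes were Sgk1 at 59.9 ± 33 TPM, Tsc22d3 at 43.2 ± 8.9 TPM and Cdkn1a at 3.77 ± 0.52 TPM, and those of the clock list Tef at 144 ± 37 TPM, Dbp at 64.7 ± 24 TPM and Cry1 at 6.22 ± 1.4 TPM. The medians of these lists were -0.06 and 0.01.

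**Figure D3:**
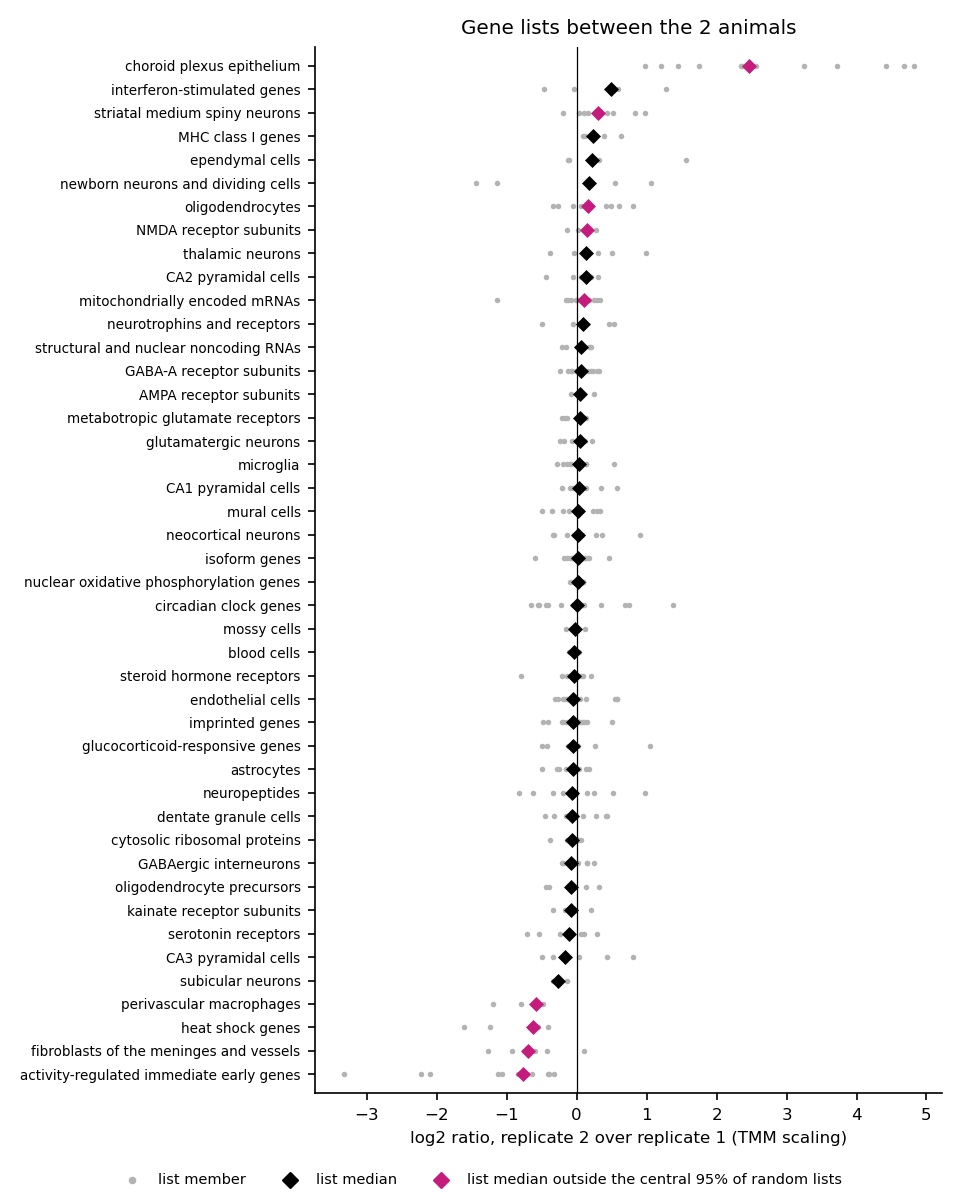
Log2 ratio of replicate 2 over replicate 1 under TMM scaling for the members (grey) and median (diamond) of each of 44 gene lists, sorted by median, with medians outside the central 95% of random lists in colour. Choroid plexus epithelium stands at 2.46 and immediate early genes at -0.76. Spike-in scaling puts the medians of oligodendrocytes, NMDA receptor subunits and mitochondrial mRNAs under 0. It moves the random lists alike, so it cannot change the place of a list among them.

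The third question was which transcript of a gene dominated. In 10029 genes with several transcripts, the highest transcript was the same in both animals for 87.6% (Clopper-Pearson interval 86.9 to 88.2%), and its median share was 60.4% in replicate 1 and 60.02% in replicate 2. Snap25 was carried by Snap25-201 at 90.3 ± 0.90%, App, the amyloid precursor, by App-201 at 90.1 ± 0.052% and Gfap, the astrocyte filament, by Gfap-201 at 91.2 ± 0.090%. Camk2a-203 held 62.8 ± 1.2% of Camk2a. The choice of table moved other genes. For Mbp, Mbp-211 held 61.2 ± 0.54% in the first table and 36.3 ± 0.57% in the second, and for the microtubule regulator Stmn2, Stmn2-201 held 65.9 ± 1.0% and 96.5 ± 2.0%. The scaffold gene Dlg4 was led by Dlg4-203 at 46.3 ± 1.1% in the first table and by Dlg4-201 at 31.2% in the second. Across genes, the tables named the same highest transcript in 80.8% (80.0 to 81.5%). This interval and that of 86.9 to 88.2% treat genes as independent, which they need not be. They do not cover the spread between animals.

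The last measurement was the spike-in share, which was 0.178% of counts in replicate 1 (Clopper-Pearson interval 0.177 to 0.179%) and 0.212% in replicate 2 (0.210 to 0.214%). For each spike-in count there were 561 other counts in replicate 1 and 471 in replicate 2. Spike-ins with counts numbered 59 and 58 of 96. The 25 spike-ins with a mean count of at least 50 had an SD of 0.12 in their log2 ratio around the spike-in total.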

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

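The tests of clock time and of genes at least 8-fold apart were chosen after the results were seen, as were the further choroid plexus genes, with their bound set before their ratios were seen, and the rule that a median over members going both ways decides nothing. Counts appeared on entries outside the comparisons. The phage phiX, a sequencing control, had 79 counts in replicate 1 and 71 in replicate 2, both above the 3 counts that a count of 0 allows. The numeric identifiers had 4 counts in replicate 1, a sum over 2 entries to which that floor does not apply. No source of these counts was tested.

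Choroid plexus markers were higher in replicate 2. Reads misassigned between gene copies do not account for it, since 0% of the 11 markers raised at least 2-fold fell under 2-fold in the second transcript table. More choroid plexus tissue in the replicate 2 sample may be the source, as a hypothesis, since 12 further choroid plexus genes, none of them among the 159 genes, had a median of 0.81, above the bound of 0.5, with members from -0.29 to 3.04 and 10 of 12 higher. Whether the ventricular wall as a whole contributed cannot be told apart, since the ependymal median was 0.22 with members from -0.13 to 1.56, a value under the bound of 0.25 set beforehand but within their spread. The design gives no biological group for a difference between these animals, and none was tested.

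Immediate early genes were lower in replicate 2. Fewer excitatory neurons in replicate 2 would lower their markers, but the glutamatergic median was 0.046 with members from -0.23 to 0.22. These members also go both ways, and the rule above was not applied to them. All lay above the immediate early median of -0.76, so they argue against a loss of excitatory neurons of that size. A GC content or length trend is also argued against, since the median after correction was -0.77. For a difference in clock time, the median of genes peaking with Per2 minus that of the Arntl arm was -0.082, with members from -0.66 to 1.38. That value met the bound written against a clock difference. Only the rule on members going both ways was applied to leave it undecided. Neuronal activity before death and the time to RNA preservation are not recorded in the labels and stay open, untested.

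At least 8-fold differences were found in 21 genes, of which 9, or 42.9%, had uncertain read assignment against 1.35% of all genes tested. That share met neither bound written for a first form of this test. In 7 of these 9, those with a mean count of at least 10 in the second table, the median size there was 15.5% of that in the first, so different assignment of reads between near-identical copies is a candidate explanation. In the other 12, all higher in replicate 2, it was 91.9%, which argues against that explanation for most of them but not for each. Among those 12, Tmem72 alone was under 2-fold in the second table, at 0.29 against 3.49 in the first. Its counts in the gene table were whole, 32 and 320, with a posterior SD of 0 in replicate 2. Shared reads thus do not account for the gene-table ratio of Tmem72, and why the second table differs was not tested. Gm17167 also shrank, from 4.65 to 1.78, so the explanation stays open for Gm17167. Several of the 12, among them Gm10600, Gm13301 and Gm17167, lie close together on chromosome 4 and are not separate cases.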

How the results depend on the processing

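The GC content and length correction and the counts without choroid plexus markers or without uncertain genes were chosen after the data were seen. Protein-coding genes held 49.9% of TPM and 88.2% of counts without mitochondrial and spike-in entries, against 81.3%. The spike-in share was 0.429% of TPM and 0.164% in the second table, against 0.195%. The Pearson r was 0.948 with a pseudocount of 0.1, 0.992 with no filter and 0.983 in the second table, against 0.977. Genes differing at least 2-fold, 159 with 85 higher and 74 lower, were 748 (464 and 284) at a mean count of at least 10 and 1253 (821 and 432) with no filter. They were 44 (16 and 28) at a mean count of at least 200 and 63 (35 and 28) with the whole interval beyond 2-fold. These settings only loosen or tighten the criterion, so the number must rise or fall. All 159 were in both larger sets, and all 44 and all 63 were among the 159. Why the split between directions moved was not tested. Spike-in scaling gave 214 (46 and 168), a shift of -0.24 in the scale between the libraries. DESeq2 size factors gave 160, TPM as deposited 192 and a prior count of 0.5 gave 168. Counts of the second table gave 171 with 103 shared, and the GC and length correction 167 with 155 shared. Without the choroid plexus markers of the fixed list there were 152, and without uncertain genes 131. Choroid plexus genes outside the fixed list were not left out of the 152. Lists higher in replicate 2 numbered 3 instead of 5 with TPM as deposited, where striatal markers at 0.13 and NMDA receptor subunits at 0.12 came inside the central 95%, and with the GC and length correction mitochondrial mRNAs did so at 0, percentile 36.2; the cause was not tested. The highest transcript was shared in 83.9% of genes at a TPM of at least 1, 90.1% at 20 and 85.4% in the second table, against 87.6%. Signs reversed for Nnt at 0.028 and mt-Co2 at 0.60 in the second table, and the cause was not tested. With spike-in scaling they reversed for oligodendrocytes at -0.085, NMDA receptor subunits at -0.098 and mitochondrial mRNAs at -0.135. That scaling lowers all genes by nearly the same amount, random lists included. The same 9 lists thus stayed outside the central 95% by construction. Of 272 ratios of named genes under alternatives, 231 kept their call, 39 lost it and 2 reversed. Of the 39, 22 lost it at a mean count of at least 200 and 6 with the whole interval beyond 2-fold. In these the ratio is unchanged and only the criterion is stricter. A further 9 lost it in the second table and 2 under spike-in scaling. Of 306 list shifts, 299 kept their place inside or outside the central 95%, 3 came inside, 1 went outside (interferon-stimulated genes, 0.55 in the second table) and 3 stayed outside with the other sign. The sign of medians inside it was not followed. DESeq2 size factors and spike-in scaling move all genes nearly alike. The 44 and 41 list shifts labelled unchanged under them are therefore no check. Of 83 summary values, 58 stayed within their spread or within 1.5 times and 25 moved. Of 276 median list levels, 153 stayed and 123 moved. With replicate 1 left out all 46 levels stayed, and with replicate 2 left out all 46 did. This was fixed in advance, since 1 of 2 values always lies within their SD of the mean. It is no check of these levels, nor of the RNA class and spike-in shares with 1 replicate left out. No paired analysis was possible because the libraries form 1 group. Depth limits genes of low count, where the median absolute log2 ratio was 0.25 at mean counts of 50 to 200 against 0.07 in the highest.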

Other observations

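The chaperone test and all genes named here were chosen after results were seen. Chaperones of the endoplasmic reticulum, which fold secreted and membrane proteins, were lower in replicate 2. Hspa5, the chaperone BiP, went from 11041 to 3139 counts, a log2 ratio of -1.56 (chromosome 2, 34771970 to 34777547). The disulfide isomerase Pdia6 was at -1.22 and Sdf2l1 at -1.32. Pdia4 and Creld2, at -1.13 and -1.03, also met the 2-fold criterion, though Creld2 was no longer called with the whole interval beyond 2-fold. From these genes came the hypothesis of a lower chaperone programme in replicate 2, tested on 10 related genes that did not meet the criterion. Not all of these 10 are chaperones, since Xbp1 and Sel1l are not. All 10 were lower, with a median of -0.65, from -0.97 for Xbp1 to -0.21 for Sel1l. The values are consistent with a shared change of this programme between 2 animals, and neither its trigger nor a difference in handling was tested.

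Other single genes differed as well. Cirbp, an RNA-binding protein of the cold response, went from 716 to 1315 counts, a log2 ratio of 1.13 (chromosome 10, 80165985 to 80172786), or 0.89 under spike-in scaling and then under the criterion. Its relative Rbm3, at 0.58, did not meet the criterion, and the processed copy Rbm3-ps did at 2.03 but not in the second transcript table, at 1.47. Whether reads were shared between Rbm3 and its copy was not tested. Enpp2, the secreted lipid enzyme autotaxin, went from 3710 to 8692 counts at 1.49, and the coagulation factor F5 was at 3.24. Both moved in the direction of the choroid plexus markers, and whether they share that shift was not tested. The circadian repressor Nfil3 was at -1.52, the thyrotropin-releasing hormone receptor Trhr at -1.20, the ghrelin receptor Ghsr at -1.25 and the thyroid hormone deiodinase Dio3 at -1.30. Trhr, Ghsr and Dio3 were no longer called with the whole interval beyond 2-fold. At a mean count of at least 200, Ghsr, Dio3 and Rbm3-ps fell under the minimum.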
